A study of Homo sapiens with 60 samples.

How the data were processed

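RNA-seq was measured in SW1783 cells, a human astrocytoma line kept in L-15 medium, 24 h after the addition of vehicle, 10 µM wortmannin or a water extract of 1 of 6 medicinal herbs at 3 doses each. The 60 libraries form 20 groups of 3, taken from the sample titles and treatment labels. The labels give 0.1% DMSO for the vehicle and the series description gives 2%, and the files do not settle which was used. The treatment labels give no DMSO content for wortmannin or the extracts. Libraries came from a directional mRNA kit and were sequenced in pairs of 100 bp reads on an MGI instrument, per the labels' protocols. The series description also says that samples with little RNA that stood out were excluded before deposit.

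The authors deposited a single table of expected counts from RSEM for 60675 gene identifiers. Adapter trimming, alignment to GRCh38 and counting used Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3, with FastQC 0.11.9 for quality checks, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Of the deposited expected counts, 11.02% were not whole numbers, and all were rounded to whole numbers before testing. A current symbol was found for 56558 identifiers, and 57055 were present in GENCODE release 29, which gave the GRCh38 coordinates and exon lengths. Total expected counts ran from 9.34 M to 35.35 M per library with a median of 25.71 M. The lowest total belonged to Liriopis_low replicate 3 and the next lowest was 18.64 M.

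All 60 libraries entered 1 quasi-likelihood fit in edgeR 4.0.16 (R 4.3.3) with a mean per group and no covariate, TMM normalisation and 40 residual degrees of freedom. A prior count of 2 was set only for log2 CPM values. Those served the principal components, the correlations and deviations of libraries, and the naming rule. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 17792. The common dispersion was 0.00761, a biological coefficient of variation of 8.72%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all tested genes within each of 28 comparisons. These were wortmannin and each dose of each herb against vehicle, the high against the low dose of each herb, and 3 pairs of herbs at high dose that share a library set. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. CPM values use the TMM-normalised library totals and are given with SD over n = 3 libraries. Unless another tool is named, every adjusted p of a gene below is from edgeR.

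Gene groups were 30 lists fixed by hand, each with at least 5 tested members, covering stress, signalling, metabolic and cell cycle programmes and markers of other cell types. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. For each list the numbers of members that rose and fell over all genes are given as a pair. A second pair, marked as list alone, gives the numbers when adjusted over the list alone, and where it is absent beside a pair of counts it was the same. A second p, marked as estimated, is that with the estimated correlation. Genes named in the text had a call, all 3 libraries beyond all 3 reference libraries and a mean of at least 5 CPM in the higher group. Symbols of clones, long intergenic or antisense transcripts and pseudogenes were passed over. The 8 largest rises and 8 largest falls were eligible per high dose or wortmannin comparison, with genes also called between high and low dose placed ahead. Comparisons of doses or of herbs used the 3 largest each way, and each list its 4 members with the smallest p. PIK3CA, PIK3CB, PIK3C3, MTOR and PLK1 were eligible whatever their values. The design, the lists, the naming rule and the alternatives were fixed before the data were examined, except those said to be chosen afterwards.

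Library sets were read here from the first part of each library name. No label calls that part a set, and every sample title names the same batch, A. Vehicle libraries belong to set A1, wortmannin to set 1, Liriopis and Schisandrae to set 2, Longan and Zizyphi to set 3, and Polygalae and Aucklandiae to set 4. A difference between sets and a difference between treatment and vehicle therefore cannot be told apart from those comparisons alone, whereas doses of a herb and paired herbs share a set. The p-values measure only the spread between these libraries, since no label says that the 3 libraries of a group came from separate cultures.

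The tests were tried on simulated counts for all 60 libraries (17221 genes). These were drawn independently from the vehicle means, the library sizes and the estimated dispersions, with changes placed in the wortmannin group. Of 100 genes changed 1.5-fold, 58 were called, or 54 of the 60 with at least 5 CPM. Of 100 genes changed 2-fold, 69 were called, or 51 of the 52 with at least 5 CPM, and 4 of 17027 unchanged genes were called. The criterion set at the start, recovery of at least 80 of the 100 genes changed 2-fold, was not met, and it was replaced afterwards by the accuracy of the recovered fold change and the share of false calls. A simulated comparison of Longan_high with vehicle in which nothing changed gave 0 calls. The simulation held no outlying library and no structure across groups, so it does not measure false calls that such features cause. Raising the mitosis list 1.2-fold gave a call for that list and for 0 others of the 30 (17230 genes).

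The alternatives were RLE size factors in edgeR, no low-count filter, the replicate number as a block, a fit of the compared groups alone, DESeq2 1.42.0 on all groups, an estimated correlation for the lists, and leaving out each library of a comparison in turn. Leaving Liriopis_high replicate 1 out of every comparison was added after the data were seen. Genes that share reads with near-identical copies (C4B, KRTAP2-3, HSPA1A and HSPA1B, SRGAP2D, the MT1 family and the NME1-NME2 readthrough) are uncertain. No library was left out of the values reported first and no deposited column went unused.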

Results

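The 60 libraries of SW1783 astrocytoma cells were compared over 17792 genes, and every group has n = 3 libraries. Gene expression moved most at the high doses of Schisandrae Fructus (500 µg/mL) and Polygalae Radix (250 µg/mL), which leave the other libraries along the first principal component (13.8% of variance). Across genes, each library correlated with the others of its group at a mean Pearson r of 0.984 or higher, except the 3 libraries of Liriopis_high (0.945, 0.967 and 0.968). The means of Liriopis_high replicates 2 and 3 include their correlation with replicate 1. Liriopis_high replicate 1 stands apart from the other libraries, mainly along the second component (12.9% of variance). By library name, vehicle libraries form a set of their own, so any contrast with vehicle also holds any set difference. The labels give no DMSO content for treated libraries, so such contrasts may hold a solvent difference too. Contrasts of dose stay within a set.

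**Figure D1:**
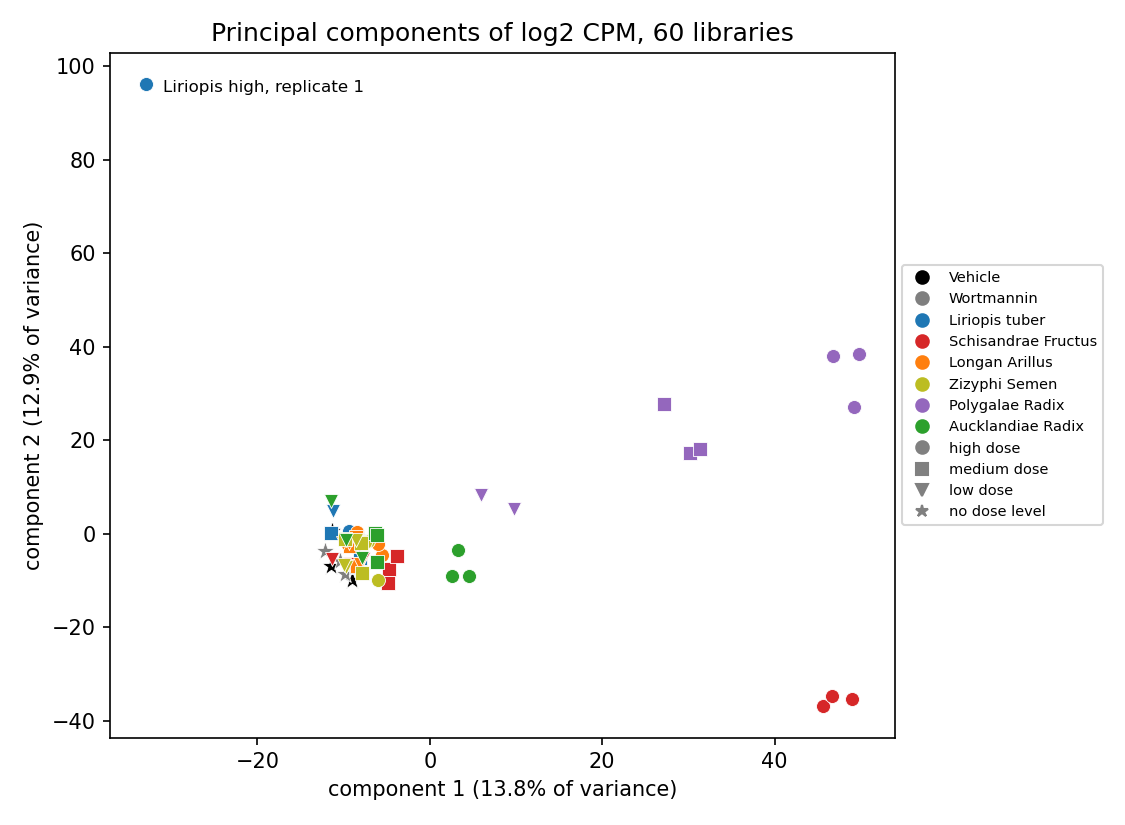
Principal components of log2 CPM for the 60 libraries, with component 1 (13.8% of variance) on the x axis and component 2 (12.9%) on the y axis, coloured by agent and shaped by dose. Schisandrae and Polygalae high doses lie to the right and Liriopis_high replicate 1 lies apart at the top left.

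**Figure D2:**
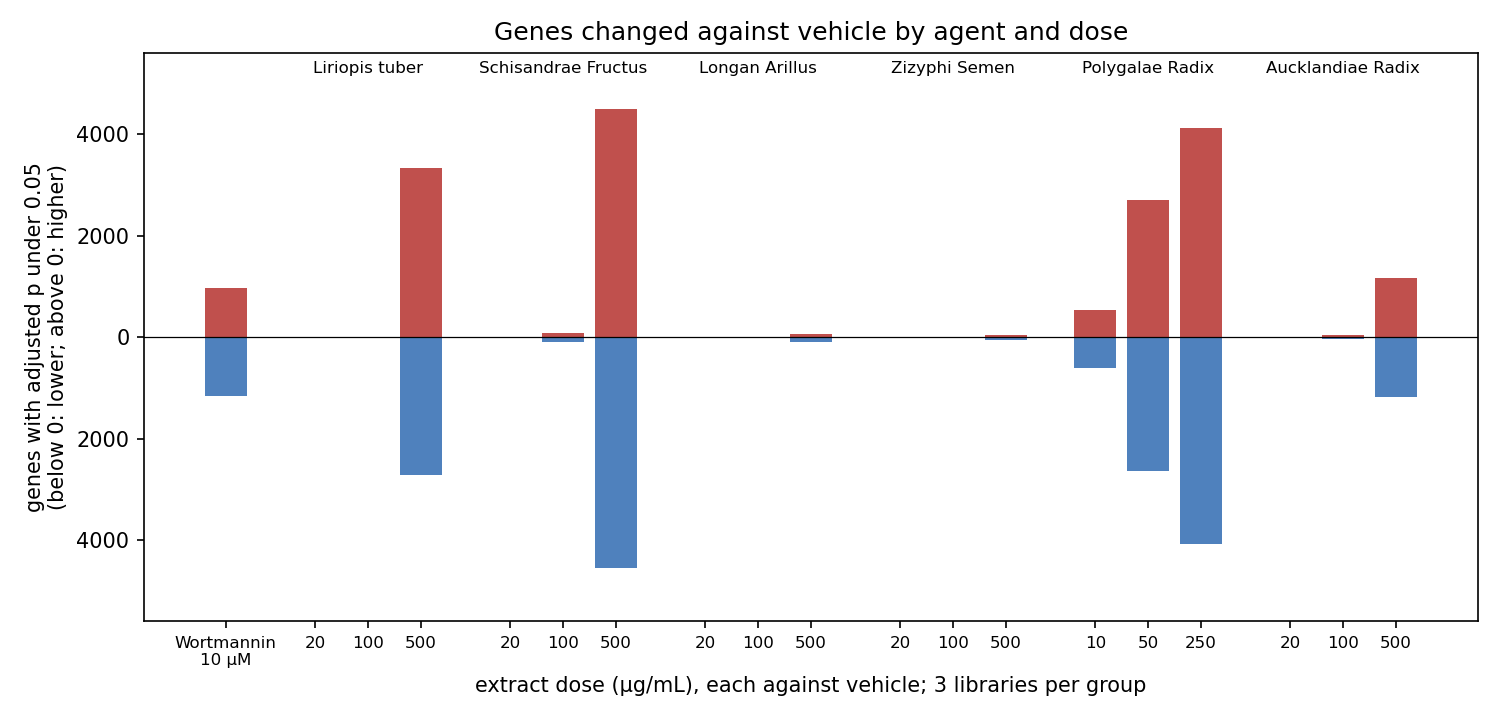
Genes higher (above 0) and lower (below 0) than vehicle at an adjusted p under 0.05 (y axis) for wortmannin and each herb dose in µg/mL (x axis), with 3 libraries per group. The tallest bars are Schisandrae high (4493 higher, 4555 lower) and Polygalae high (4115 higher, 4079 lower).

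Under wortmannin, an inhibitor of phosphatidylinositol 3-kinases, genes of cell division were lower than in vehicle, and ITGB4 and the insulin-repressed gene IGFBP1 were higher. ITGB4, an integrin subunit (ENSG00000132470, chromosome 17, 75721328 to 75757818, plus strand), rose from 26.4 (SD 0.666) to 65.6 (SD 3.43) CPM (log2 1.31, SE 0.11, adjusted p = 2.4e-12). IGFBP1, which encodes a binding protein of insulin-like growth factors, rose from 9.8 (SD 0.883) to 22.6 (SD 1.35) CPM (log2 1.21, SE 0.12, adjusted p = 1.1e-09). MYBL2, a cell cycle transcription factor, had a log2 fold change of -0.84 (SE 0.07, adjusted p = 3e-12), and HMOX1, which encodes heme oxygenase, had the same fold change (SE 0.1, adjusted p = 2.1e-08). In all, 969 genes rose and 1160 fell, 73 of them by 2-fold or more, and without Liriopis_high replicate 1 in the common fit the count was 4108.

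The mitosis list fell under wortmannin, with 19 of 24 members lower over all genes and 20 when adjusted over the list alone (adjusted p = 6.1e-21, and 8.3e-06 with an estimated correlation), among them CDC20 (-0.52), AURKA (-0.37) and PLK1 (-0.34). In the DNA replication list 13 of 24 fell (list alone 17, adjusted p = 3.2e-17, estimated 2e-05), including RRM2 (-0.48) and CDC6 (-0.45). Genes of hypoxia and glycolysis fell (11 of 24, list alone 12, adjusted p = 1.1e-05, estimated 0.0043), with LDHA at -0.33. Feedback genes of the ERK pathway rose, with 5 higher and 1 lower of 13 (list alone 7 and 1, adjusted p = 6.6e-07, estimated 0.0028), such as DUSP4 (0.49) and ETV1 (0.74). The FOXO target list did not pass (adjusted p = 0.068, estimated 0.19) although 5 of its 19 members rose and 3 fell (list alone 6 and 3), with KLHL24 at 0.62 and PIK3IP1 at 1.17.

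Of the other lists under wortmannin, 5 passed at the preset correlation but not with an estimated one. NRF2 targets (0 up, 7 down of 24, list alone 1 and 9, adjusted p = 0.0035, estimated 0.19), the unfolded protein response (0 and 3 of 19, 0.013, estimated 0.19) and heat shock (1 and 5 of 17, 0.013, estimated 0.2) moved down. Extracellular matrix (6 and 0 of 23, list alone 9 and 0, 0.0061, estimated 0.61) and lysosome and autophagy (9 and 1 of 29, list alone 10 and 1, 0.013, estimated 0.13) moved up. The lysosome call ended, at an adjusted p of up to 0.065, without Vehicle replicate 3 or Wortmannin replicate 3. Of the kinases that wortmannin is known to inhibit, PIK3CA (0.01, adjusted p = 0.97), PIK3CB (-0.19, 0.078) and MTOR (-0.19, 0.63) did not pass. PIK3C3 rose (0.27, SE 0.08, 0.017), a call that ended without Vehicle replicate 1 or Wortmannin replicate 1. PLK1, given above with the mitosis list, fell (-0.34, SE 0.05, adjusted p = 5.3e-06). All of these are transcript levels, which do not measure inhibition of the kinases. By library name, the vehicle (A1) and wortmannin (1) libraries belong to different sets, though no label calls these sets. A set difference and the drug therefore cannot be told apart here.

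Schisandrae Fructus at the high dose raised TXNIP, a brake on glucose uptake that glucose itself induces (ENSG00000265972, chromosome 1, 145992435 to 145996600, minus strand), from 10.1 (SD 0.265) to 358 (SD 5) CPM, a log2 fold change of 5.15 (SE 0.1, adjusted p = 2.6e-37). Its relative ARRDC4 rose with it (2.71, SE 0.1, adjusted p = 6.1e-26). CXCL8, a neutrophil chemokine (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand), rose from 2.98 (SD 0.369) to 67.6 (SD 3.44) CPM (log2 4.5, SE 0.13), and THBD, which encodes thrombomodulin, rose from 9.36 (SD 0.571) to 112 (SD 2.32) CPM (log2 3.58, SE 0.09). The serotonin receptor gene HTR2A (-3.79, SE 0.15), the R-spondin receptor gene LGR6 (-3.89, SE 0.18) and the integrin gene ITGB8 (-3.29, SE 0.15) fell. At this dose 4493 genes rose and 4555 fell, 1953 by 2-fold or more. At the medium dose 82 rose and 100 fell, with TXNIP already at 1.29 (adjusted p = 3.1e-13), and at the low dose edgeR called 0 genes (429 at an unadjusted p under 0.05) and DESeq2 called 3. The medium count of 182 was 842 without Liriopis_high replicate 1, 120, 99 and 73 without Vehicle replicates 1, 2 and 3, and 84 and 81 without its own replicates 2 and 3.

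Amino acid stress genes under ATF4 rose with Schisandrae, with 25 of 27 targets higher over all genes and also adjusted over the list alone (adjusted p = 2.6e-25, estimated 1.1e-09), such as TRIB3 (1.85), SESN2 (1.66) and VLDLR (1.45). NF-kB and cytokine genes rose, with 16 up and 4 down of 22 (adjusted p = 2e-11, estimated 2.2e-08), including IL1B (2.98) and PTGS2 (2.09). The unfolded protein response rose (12 up, 1 down of 19, list alone 13 and 1, adjusted p = 5.2e-07, estimated 0.0056), with ERN1 at 1.33 and HSPA5 at 1.16. The cell cycle lists split, since mitosis rose (19 up, 0 down of 24, adjusted p = 4.4e-06, estimated 0.015, CCNA2 0.82) and DNA replication fell (0 and 19 of 24, list alone 0 and 20, adjusted p = 4.4e-10, estimated 0.00095, MCM3 -1.45).

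ERK feedback (9 up, 1 down of 13, adjusted p = 5.4e-08, estimated 0.00095, PHLDA1 1.4) and immediate early genes (10 and 3 of 17, 0.0015, estimated 0.025, DUSP1 1.92) rose with Schisandrae, as did p53 targets (13 and 3 of 20, list alone 13 and 4, 0.014, estimated 0.015, TNFRSF10B 1.16). Neuron markers fell on balance (2 and 5 of 7, 0.00028, estimated 0.0011, SNAP25 -1.67). NRF2 targets (13 and 5 of 24, 0.014), hypoxia and glycolysis (9 and 7 of 24, 0.021, NDRG1 1.75) and, downward, astrocyte markers (0 and 6 of 8, 0.0075, SLC1A3 -1.61) passed at the preset correlation but not with an estimated one (0.33, 0.13 and 0.13).

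Between the high and low doses of Schisandrae, whose libraries share a set, 4440 genes rose and 4407 fell, 1854 by 2-fold or more. TXNIP (5.07), CXCL8 (4.53) and LGR6 (-3.78) kept nearly their full fold. ATF4 targets rose in 24 of 27 members and fell in 0 (adjusted p = 3.1e-24, estimated 2e-09), and NF-kB genes rose (16 and 4 of 22, 5.4e-12, estimated 1.2e-08). Calls held with an estimated correlation also for ERK feedback (5e-09, estimated 0.00054), mitosis (7.5e-07, 0.0077), the unfolded protein response (5.5e-07, 0.0054), DNA replication (3.6e-09, 0.0014), neuron markers (0.00027, 0.0014), immediate early genes (0.00097, 0.019) and p53 targets (0.0079, 0.008). Heat shock (0.032, estimated 0.32), NRF2 targets (0.018, 0.34), interferon-stimulated genes (0.032, 0.42), hypoxia (0.04, 0.21) and astrocyte markers (0.018, 0.2) passed at the preset correlation alone. Leaving out Liriopis_high replicate 1 ended the heat shock call (0.062), leaving out it or Schisandrae_high replicate 2 or 3 ended the interferon call (up to 0.064), and leaving out Schisandrae_low replicate 2 or 3 ended the hypoxia call (up to 0.055).

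Polygalae Radix raised GDF15 and HMOX1 and lowered COL1A2 and TNC, and these 4 genes moved further at each higher dose. GDF15, a stress-induced cytokine (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand), rose from 2.88 (SD 0.508) to 124 (SD 9.84) CPM at 250 µg/mL (log2 5.43, SE 0.15, adjusted p = 3.7e-31), with 4.07 at the medium and 1.77 at the low dose. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand) rose from 56.5 (SD 1.38) to 999 (SD 21.3) CPM (log2 4.14, SE 0.11, then 3.61 and 1.9 at the lower doses). The collagen gene COL1A2 (ENSG00000164692, chromosome 7, 94394561 to 94431232, plus strand) fell from 1800 (SD 46.7) to 261 (SD 16.3) CPM (log2 -2.79, SE 0.08, then -1.5 and -0.55). The tenascin gene TNC fell from 789 (SD 22.9) to 76.3 (SD 12.6) CPM (log2 -3.37, SE 0.21, then -1.8 and -0.71). Against vehicle, 4115 genes rose and 4079 fell at the high dose (1401 by 2-fold or more), 2707 and 2649 at the medium dose (599) and 535 and 615 at the low dose (64). The low dose total of 1150 was 2512 without Liriopis_high replicate 1, 748 and 728 without Vehicle replicates 2 and 3, and 659 without its own replicate 2. The composition of the high dose libraries differed too, with 12.5, 13.4 and 12.4% of counts on mitochondrial genes against 10.3, 10.4 and 10.6% in vehicle, and TMM factors of 1.08, 1.10 and 1.12 against 0.984, 0.977 and 0.979.

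All 23 extracellular matrix genes fell at the high dose of Polygalae, over all genes and adjusted over the list alone (adjusted p = 1.5e-40, estimated 0.00082), with a median log2 fold change of -1.25 and COL3A1 at -2.85. Genes of lysosome and autophagy rose (21 up, 4 down of 29, adjusted p = 1e-15, estimated 6e-07), led by GPNMB (2.38) and SQSTM1 (2.05). Targets of the oxidant-responsive transcription factor NRF2 rose (14 and 3 of 24, list alone 16 and 3, 9.8e-20, estimated 0.0002), including OSGIN1 (2.81), SRXN1 (1.84) and TXNRD1 (1.82). The unfolded protein response fell (3 and 12 of 19, 3.8e-09, estimated 0.00099), with the chaperone genes HSPA5 (-1.9), HYOU1 (-1.56) and HSP90B1 (-1.41). Interferon-stimulated genes rose (16 and 2 of 24, list alone 17 and 3, 1.1e-07, estimated 0.025), such as IFIT2 (2.86), IFIT3 (2.33) and OASL (2.15).

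The lists of mitosis, DNA replication, and hypoxia and glycolysis moved down on balance with Polygalae, though some members of the latter lists rose. Mitosis had 0 up and 19 down of 24 (list alone 0 and 20, adjusted p = 5.8e-08, estimated 0.003, KIF20A -1.55). DNA replication had 4 and 15 of 24 (0.00012, estimated 0.021, RRM1 -0.96), and hypoxia and glycolysis 6 and 14 of 24 (list alone 7 and 14, 1.4e-06, estimated 0.0014, LDHA -1.43, PKM -1.41). ERK feedback (9 and 0 of 13, 3.4e-08, estimated 0.0008) and p53 targets (10 and 2 of 20, 0.0002, estimated 0.0008, CDKN1A 1.06) went upward. FOXO targets (10 and 3 of 19, 0.00057, estimated 0.0071, FBXO32 1.99) rose, as did immediate early genes (9 and 1 of 17, list alone 10 and 1, 0.00073, estimated 0.016) and NF-kB genes (12 and 6 of 22, 0.021, estimated 0.02, LIF 2.48, IL11 -0.89). Fatty acid synthesis (0 and 11 of 13, 0.00017, estimated 0.098, FASN -1.65, ACLY -1.29), heat shock (8 and 4 of 17, upward, 0.0015, estimated 0.079) and the nuclear-encoded respiratory chain (0 and 7 of 23, 0.0073, estimated 0.55) passed at the preset correlation alone.

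Between 250 and 10 µg/mL of Polygalae, in libraries of a single set, 3182 genes rose and 3251 fell, 644 by 2-fold or more, with GDF15 at 3.65 and TNC at -2.65. The matrix list again fell in 23 of 23 members (adjusted p = 3.4e-43, estimated 0.00039). Calls in the same direction as against vehicle held with an estimated correlation for NRF2 targets (1.1e-17, estimated 0.00019), mitosis (9.7e-15, 0.00013), ERK feedback (6.6e-12, 0.00013), lysosome and autophagy (7.4e-08, 0.00019), the unfolded protein response (3.9e-08, 0.0015), hypoxia (1.1e-06, 0.00098) and p53 targets (5.4e-05, 0.00019). They also held for NF-kB genes (8.1e-05, 0.0002), immediate early genes (9.1e-06, 0.0017) and FOXO targets (0.0092, 0.041). DNA replication (0.0019, estimated 0.072), fatty acid synthesis (0.00064, 0.14), heat shock (0.007, 0.14), interferon-stimulated genes (8.2e-05, 0.11) and the nuclear-encoded respiratory chain (0.0003, 0.41) passed at the preset correlation alone. So did YAP and TGF-beta targets downward (0.04, estimated 0.31, with a median of 0.02 above 0 and a mean of -0.17 below it), a call that ended without Polygalae_high replicate 2 (0.071), and mitochondrially encoded genes upward (0.025, estimated 0.47), which ended without Polygalae_low replicate 2 (0.2).

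Aucklandiae Radix at 500 µg/mL raised ANGPTL4, a secreted inhibitor of lipoprotein lipase (ENSG00000167772, chromosome 19, 8363289 to 8374373, plus strand), from 12.9 (SD 0.873) to 91.9 (SD 7.26) CPM (log2 2.84, SE 0.1, adjusted p = 8.4e-27). CXCL8 (1.83, SE 0.13) and THBD (1.81, SE 0.09) rose, and LGR6 (-2.17, SE 0.14), SAMD11 (-1.34, SE 0.1) and the pro-apoptotic gene BMF (-1.84, SE 0.15) fell. At the high dose 1163 genes rose and 1190 fell, 227 by 2-fold or more, against 38 and 43 at the medium dose. Only CCN1, a matricellular gene named after its value was seen, passed at the low dose (0.45, adjusted p = 0.0021, with 631 genes at an unadjusted p under 0.05). Without Liriopis_high replicate 1 the high, medium and low totals of 2353, 81 and 1 were 4126, 271 and 16. The medium total was 45 and 47 without Vehicle replicates 2 and 3 and 52 and 46 without its own replicates 2 and 3, and the low total was 0 without its own replicate 3.

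NRF2 targets rose with Aucklandiae, with 20 up and 0 down of 24 (list alone 22 and 0, adjusted p = 2.2e-48, estimated 3.7e-08), among them HMOX1 (1.4), SRXN1 (0.88), TXNRD1 (0.84) and GCLM (0.7). ERK feedback rose (8 and 0 of 13, list alone 9 and 0, 4.4e-24, estimated 3.7e-08), with DUSP5 at 1.1 and DUSP6 at 1.02. Hypoxia and glycolysis rose (10 and 0 of 24, list alone 11 and 0, 1.2e-12, estimated 9.9e-06), with NDRG1 at 0.96 and VEGFA at 0.75. Also higher were NF-kB genes (11 and 3 of 22, list alone 13 and 3, 3.9e-05, estimated 0.00012) and immediate early genes (7 and 0 of 17, list alone 7 and 1, 5.7e-06, estimated 0.002). ATF4 targets (8 and 3 of 27, list alone 10 and 4, 0.0029, estimated 0.029, SLC7A11 0.98) and aryl hydrocarbon receptor targets (3 and 0 of 7, 0.017, estimated 0.029, NQO1 0.91) rose. Cholesterol synthesis fell (1 and 6 of 25, list alone 1 and 7, 0.0062, estimated 0.0064, INSIG1 -0.37).

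With Aucklandiae, 4 lists fell at the preset correlation but not with an estimated one. They were extracellular matrix (0 and 9 of 23, list alone 0 and 13, adjusted p = 3.6e-10, estimated 0.15, COL1A1 -0.86) and interferon-stimulated genes (0 and 6 of 24, list alone 0 and 9, 0.00095, estimated 0.24, IFI44L -0.72). The others were heat shock (2 and 5 of 17, list alone 3 and 7, 0.014, estimated 0.24) and leukocyte markers (0 and 2 of 5, 0.045, estimated 0.15). The heat shock call ended without Aucklandiae_high replicate 2 (0.051), and the leukocyte call without Vehicle replicate 1 or Aucklandiae_high replicate 1 or 3 (up to 0.098).

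High and low doses of Aucklandiae differed in 947 genes upward and 943 downward (3489 in total without Liriopis_high replicate 1), 174 by 2-fold or more, with ANGPTL4 at 2.88 and SAMD11 at -1.59. NRF2 targets rose (18 and 0 of 24, list alone 20 and 0, adjusted p = 1.7e-39, estimated 2e-07), as did ERK feedback (7.8e-25, estimated 6.6e-08), hypoxia and glycolysis (1.4e-14, 2.3e-06), NF-kB genes (0.00014, 0.00041) and immediate early genes (0.00012, 0.0086), and cholesterol synthesis fell (0.0043, 0.0049). At the preset correlation alone, extracellular matrix (4.3e-06, estimated 0.27), interferon-stimulated genes (4.3e-06, 0.097), heat shock (0.0061, 0.2), YAP and TGF-beta targets (0.029, 0.3) and mitosis (0.027, 0.26) fell, and aryl hydrocarbon receptor targets (0.029, 0.057) and ATF4 targets (0.027, 0.12) rose. The ATF4 call ended without Aucklandiae_high replicate 3 (0.078), the YAP call without Aucklandiae_high replicate 1 or Aucklandiae_low replicate 3 (up to 0.13), and the mitosis call without Aucklandiae_high replicate 1 or 2 or Aucklandiae_low replicate 3 (up to 0.087).

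Longan Arillus, a sugar-rich fruit, raised the glucose-responsive pair TXNIP and ARRDC4 at 500 µg/mL. TXNIP rose from 10.1 (SD 0.265) to 59.2 (SD 3.05) CPM (log2 2.55, SE 0.09, adjusted p = 2.5e-25), and ARRDC4 from 5.41 (SD 1.02) to 12.2 (SD 0.527) CPM (log2 1.17, SE 0.11, adjusted p = 1.6e-10). The endoplasmic reticulum chaperone gene HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330, minus strand) fell from 3280 (SD 84.7) to 2280 (SD 102) CPM (log2 -0.52, SE 0.06, adjusted p = 2.9e-07). FAM13B (-0.78, SE 0.11) and the ubiquitin ligase gene FBXO32 (-0.52, SE 0.08) fell too, and CXCL8 (0.8, SE 0.14) rose. The high dose total was 150 genes (53 up, 97 down, 6 by 2-fold or more). It became 1269 without Liriopis_high replicate 1, 37 and 54 without Vehicle replicates 2 and 3, and 77 and 39 without its own replicates 1 and 3.

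The lower Longan doses called few genes, named after their values were seen. At the medium dose PADI2 (-0.56, adjusted p = 0.044), CHI3L1 (-0.4, 0.0013), LGR6 (-0.61, 0.038), SFRP2 (-0.34, 0.021) and CADM3 (-0.31, 0.022) fell (606 genes at an unadjusted p under 0.05), and at the low dose SFRP2 fell (-0.34, 0.035, 467 genes). LGR6, called at the medium doses of Longan, Zizyphi and Liriopis, also lay below vehicle without passing at the low doses of Longan (-0.41), Zizyphi (-0.4), Liriopis (-0.35) and Aucklandiae (-0.41). It did not pass from low to high dose of Longan (-0.33, adjusted p = 0.41), Zizyphi (-0.32, 0.39) or Liriopis (-0.17, 0.38), so for Longan and Zizyphi, which share a set, a set difference and the extract cannot be told apart. Schisandrae low, in the set of Liriopis, lay close to vehicle (-0.11, SE 0.12). The medium count was 10 without Liriopis_high replicate 1, 0, 1 and 1 without Vehicle replicates 1, 2 and 3, and 2 without any of its own libraries. The low count was 3 without Liriopis_high replicate 1 and 0 without any vehicle library or its own replicate 1 or 2.

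The unfolded protein response list fell with Longan at the high dose, with 0 up and 5 down of 19 over all genes and 12 down adjusted over the list alone (adjusted p = 3.2e-13, estimated 0.00029), including HSP90B1 (-0.29). Lysosome and autophagy (0 and 2 of 29, list alone 0 and 5, 9e-06, estimated 0.0023) and FOXO targets (0 and 2 of 19, list alone 0 and 3, 0.0016, estimated 0.02) moved down. The same holds for ATF4 targets (0 and 1 of 27, list alone 0 and 3, 0.0012, estimated 0.02) and metallothioneins (0 and 0 of 5, list alone 0 and 3, 0.00096, estimated 0.02). Mitosis (0 and 0 of 24, list alone 5 and 0, 9.8e-07, estimated 0.011) and NF-kB genes (4 and 0 of 22, list alone 7 and 1, 0.00053, estimated 0.0013, IL1B 0.59) moved up. NRF2 targets upward (1 and 0 of 24, list alone 4 and 0, 0.00092, estimated 0.14) and extracellular matrix downward (0 and 0 of 23, 0.00092, estimated 0.4) passed at the preset correlation alone. So did immediate early genes upward (1 and 0 of 17, list alone 2 and 1, 0.04, estimated 0.14) and astrocyte markers downward (0 and 0 of 8, list alone 0 and 1, 0.049, estimated 0.23). The matrix call ended without Longan_high replicate 2 (0.053), the immediate early call without Vehicle replicate 1 or Longan_high replicate 1 or 3 (up to 0.13), and the astrocyte call without Vehicle replicate 2 or 3 or Longan_high replicate 2 (up to 0.1).

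High against low Longan, within a single set, kept TXNIP (2.63, SE 0.09), ARRDC4 (1.13, SE 0.11) and HSPA5 (-0.43, adjusted p = 3.7e-05). The total of 44 genes (22 up, 22 down) was 329 without Liriopis_high replicate 1, 20, 22 and 17 without Longan_high replicates 1, 2 and 3, and 13, 20 and 26 without Longan_low replicates 1, 2 and 3. Calls held with an estimated correlation for the unfolded protein response (0 and 3 of 19, list alone 0 and 10, adjusted p = 2.2e-10, estimated 0.0018), lysosome (2.2e-05, 0.004), ATF4 targets (0.00023, 0.009) and metallothioneins (0.00083, 0.018) downward. Upward they held for mitosis (0.00019, estimated 0.04), immediate early genes (1.2e-05, 0.004), ERK feedback (0.00033, 0.022), NF-kB genes (0.002, 0.0044), NRF2 targets (1.2e-05, 0.043) and aryl hydrocarbon receptor targets (0.0065, 0.018). At the preset correlation alone, DNA replication (0.0022, estimated 0.089), heat shock (0.0018, 0.09) and histones (0.029, 0.12) rose, and FOXO targets (0.037, 0.09) and extracellular matrix (0.042, 0.6) fell. The FOXO call ended without Liriopis_high replicate 1, Longan_low replicate 1 or Longan_high replicate 2 or 3 (up to 0.21). The matrix call ended without Longan_low replicate 1 or 3 or Longan_high replicate 2 (up to 0.53), and the histone call without Longan_low replicate 1 or Longan_high replicate 1 or 3 (up to 0.091).

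Zizyphi Semen at 500 µg/mL raised CXCL8 and PLIN2 and lowered SAMD11 and the BMP-responsive genes ID3 and ID2. CXCL8 rose from 2.98 (SD 0.369) to 5.93 (SD 0.324) CPM (log2 0.99, SE 0.14, adjusted p = 1.3e-05), and the lipid droplet gene PLIN2 rose (0.53, SE 0.06, adjusted p = 3.7e-07). SAMD11 (ENSG00000187634, chromosome 1, 923928 to 944581, plus strand) fell from 127 (SD 4.58) to 74.1 (SD 1.48) CPM (log2 -0.78, SE 0.09, adjusted p = 5.7e-07). The lower genes ID3 (-0.78, SE 0.15, adjusted p = 0.0021) and ID2 (-0.71, SE 0.1, adjusted p = 1.7e-05) encode inhibitors of differentiation. Of 108 genes called at the high dose, 44 rose and 64 fell, 7 by 2-fold or more. The total was 420 without Liriopis_high replicate 1, 58 and 71 without Vehicle replicates 2 and 3, and 64, 56 and 56 without its own replicates 1, 2 and 3.

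At the medium dose of Zizyphi 7 genes passed (779 at an unadjusted p under 0.05), 1 of them higher, CCN1 (0.36), and 6 lower, including PADI2 (-0.56) and LGR6 (-0.63), all named after their values were seen. That count was 16 without Liriopis_high replicate 1 and 0 without any vehicle library or any of its own. At the low dose edgeR called 0 genes (744 at an unadjusted p under 0.05, and 1 without Liriopis_high replicate 1) and DESeq2 called 3.

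The NF-kB list rose with Zizyphi at the high dose (4 up, 1 down of 22, list alone 9 and 1, adjusted p = 4.1e-11, estimated 4.4e-08), with IL1B at 0.57 and, downward, IL11 at -0.44. ATF4 targets moved up (0 and 0 of 27, list alone 3 and 0, 0.00016, estimated 0.01). NRF2 targets upward (0 and 0 of 24, 0.00053, estimated 0.25) and fatty acid synthesis downward (0 and 1 of 13, list alone 0 and 2, 0.00053, estimated 0.27, MID1IP1 -0.24) passed at the preset correlation alone. So did DNA replication downward (0 and 0 of 24, list alone 0 and 2, 0.0074, estimated 0.25) and extracellular matrix downward (0 and 0 of 23, 0.023, estimated 0.66). The replication call ended without Vehicle replicate 1 or Zizyphi_high replicate 2 (up to 0.15), and the matrix call without Vehicle replicate 1 or 2 or Zizyphi_high replicate 1 (up to 0.1).

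From low to high Zizyphi, CXCL8 (1.23), ANGPTL4 (0.81) and LIF (0.64) rose, and SAMD11 (-0.96) and ID3 (-0.94) fell. The total of 120 genes (52 up, 68 down) was 518 without Liriopis_high replicate 1, 69 and 68 without Zizyphi_high replicates 1 and 2, and 71 and 79 without Zizyphi_low replicates 2 and 3. NF-kB genes (3 and 1 of 22, list alone 7 and 1, adjusted p = 9.2e-12, estimated 2.2e-08) and ATF4 targets (0 and 0 of 27, list alone 4 and 0, 0.00024, estimated 0.018) rose as lists. At the preset correlation alone, NRF2 targets (0.00012, estimated 0.13) and FOXO targets (0.027, 0.13) rose, and fatty acid synthesis (0.00012, 0.18), interferon-stimulated genes (0.0048, 0.39) and LXR targets (0.027, 0.067) fell. Of these, the FOXO call ended without Zizyphi_low replicate 1 or 2 or Zizyphi_high replicate 2 (up to 0.11), and the LXR (up to 0.082) and interferon (up to 0.059) calls without Zizyphi_low replicate 1 or 3 or Zizyphi_high replicate 2.

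Gene calls for the tuber of Liriopis or Ophiopogon at 500 µg/mL rest on a single library. With all 3 libraries, 3334 genes rose and 2711 fell against vehicle, but without Liriopis_high replicate 1 only ANKH passed, a gene for a pyrophosphate transporter (-0.22, SE 0.04, adjusted p = 0.015, with 1287 of 18078 genes at an unadjusted p under 0.05). In a fit of the 6 libraries alone edgeR called 0 genes, whereas the common fit called 3405 and 2546 without Vehicle replicates 2 and 3. RPL39, a ribosomal protein gene, illustrates the spread at 620 (SD 469) CPM against 297 (SD 27.1) in vehicle. Between high and low doses the total of 2864 (2105 up, 759 down) was 0 without Liriopis_high replicate 1 (1058 genes at an unadjusted p under 0.05), 7371 and 7190 without its replicates 2 and 3, and 1832, 12 and 439 without Liriopis_low replicates 1, 2 and 3.

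With all libraries, cytosolic ribosomal proteins (24 up, 0 down of 24, adjusted p = 2.2e-10) and the nuclear-encoded respiratory chain (21 and 0 of 23, 2e-09) were higher in Liriopis_high, and extracellular matrix was lower (0 and 18 of 23, 9.2e-08). ATF4 targets (12 and 1 of 27, list alone 13 and 2, 0.016) and NRF2 targets (11 and 1 of 24, list alone 12 and 1, 0.014) moved up. Fatty acid synthesis (0 and 6 of 13, list alone 0 and 9, 0.0033) and astrocyte markers (0 and 5 of 8, list alone 0 and 7, 0.014) moved down. With an estimated correlation each of these 7 had an adjusted p of 0.53. Without Liriopis_high replicate 1 no member of these lists passed over all genes. ATF4 targets (3.4e-05, estimated 0.033), matrix (2.4e-05, estimated 0.29), the respiratory chain (0.0019, estimated 0.49), ribosomal proteins (0.022, estimated 0.63), astrocyte markers (0.0085, estimated 0.12) and fatty acid synthesis (0.046, estimated 0.37) still passed as lists at the preset correlation, and NRF2 targets did not (0.16). Mitochondrially encoded genes, not called with all libraries, passed downward without Liriopis_high replicate 1 (0.0038, estimated 0.49, median -0.15). Leaving out Liriopis_high replicate 2 or 3 ended the ATF4 call (up to 0.068).

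High against low Liriopis gave the same kind of result, with ribosomal proteins (18 and 0 of 24, list alone 24 and 0, adjusted p = 7.1e-09), the respiratory chain (1.2e-08) and NRF2 targets (0.0081) up. Extracellular matrix (1.7e-06) and fatty acid synthesis (0.0068) were down, and each of the 5 was at 0.48 with an estimated correlation. Without Liriopis_high replicate 1 the calls ended for NRF2 targets (0.37), matrix (0.37), fatty acid synthesis (0.77) and the respiratory chain (0.72, with its direction reversed), and ribosomal proteins were called in the opposite direction (0.0026). At the medium dose CHI3L1 (-0.39, adjusted p = 0.0025) and LGR6 (-0.67, adjusted p = 0.021) fell, and at the low dose SDCBP2 rose (2.47, adjusted p = 0.029), all named after their values were seen, with 560 and 990 genes at an unadjusted p under 0.05. Those counts were 7 and 5 without Liriopis_high replicate 1. The medium count was 1 without Vehicle replicate 3, 0 without its own replicate 2 and 1 without its own replicate 3, and the low count was 0 without any vehicle library or any of its own.

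**Figure D3:**
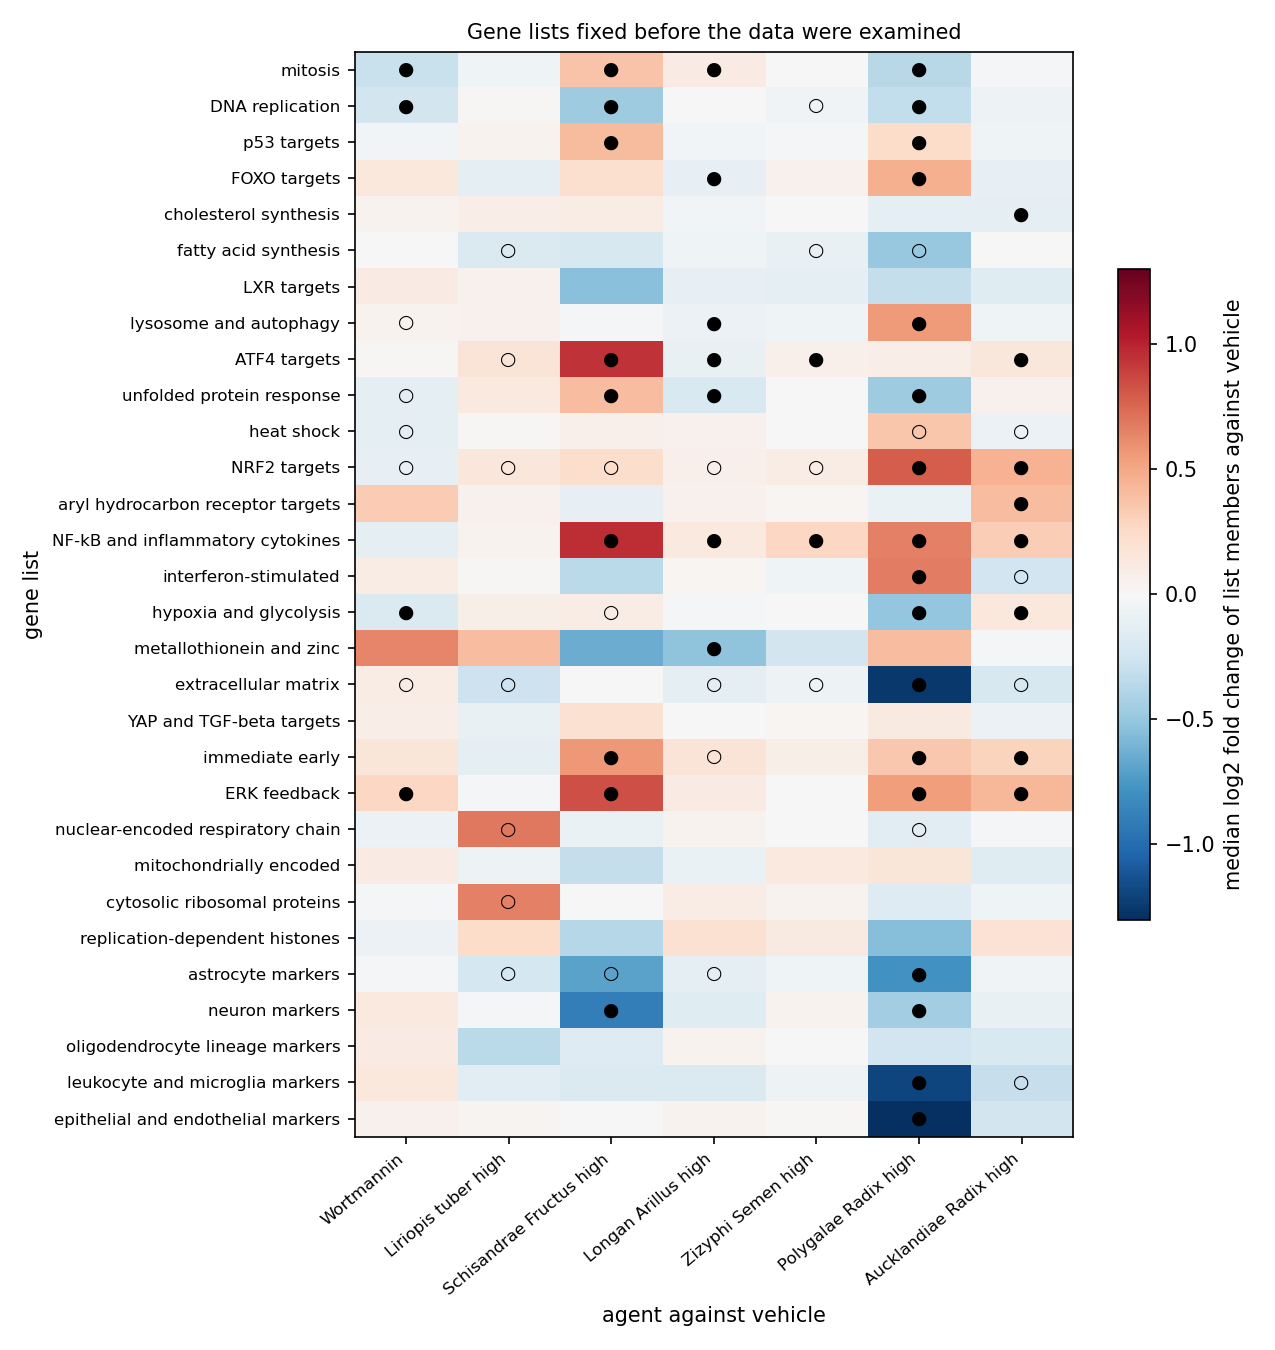
Median log2 fold change of the members of each of 30 gene lists (y axis) for wortmannin and each herb's high dose against vehicle (x axis), with n = 3 libraries per group. Filled circles passed with both the preset and an estimated correlation and open circles with the preset correlation alone, and the lowest medians among the filled circles are those of epithelial and endothelial markers (-1.61) and the matrix list (-1.25) with Polygalae.

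The marker lists were tested on the members expressed in this single cell line. These were 8 of 15 for astrocytes, 7 of 12 for neurons, 5 of 11 for leukocytes and microglia, and 6 of 11 for epithelium and endothelium. The lists therefore do not measure which cell types are present. Genes of several marker lists fell with Polygalae. At its high dose, astrocyte markers (0 up, 5 down of 8, list alone 0 and 6, adjusted p = 4.3e-05, estimated 0.012, VIM -1.35) and neuron markers (1 and 4 of 7, 0.0027, estimated 0.0071) fell. So did leukocyte and microglia markers (0 and 3 of 5, 0.0029, estimated 0.02, PTPRC -2.7) and epithelial and endothelial markers (0 and 5 of 6, list alone 0 and 6, 0.0059, estimated 0.012, KRT18 -1.89). Between its high and low doses astrocyte (0.00023, estimated 0.024), neuron (0.0015, 0.0034) and epithelial (0.0081, 0.016) markers fell, and leukocyte markers fell at the preset correlation alone (0.013, 0.063). Oligodendrocyte lineage markers passed in none of the 13 comparisons tested with lists, with adjusted p of 0.39 for Polygalae and 0.91 for Schisandrae at the high dose.

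With all libraries in the fit, several lists did not pass for any high dose or wortmannin against vehicle. LXR targets had their lowest adjusted p with Zizyphi (0.056, 0 and 0 of 10), and so had mitochondrially encoded genes (0.054, 0 and 0 of 13). The lowest for replication-dependent histones was with Polygalae (0.21, 1 and 4 of 9), and for YAP and TGF-beta targets with Schisandrae (0.07, 7 and 3 of 15, list alone 7 and 4). Ribosomal proteins passed for Liriopis alone and reached 0.072 with Longan and 0.39 with Polygalae (0 and 4 of 24, list alone 0 and 1).

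Against vehicle, median, mean and test differed in sign for some lists that did not pass. With wortmannin these were YAP and TGF-beta targets (median 0.09, mean -0.01, test down), p53 targets (-0.04, 0.02, up), astrocyte markers (-0.03, 0.04, up) and ATF4 targets (0.02, 0, down). Schisandrae gave aryl hydrocarbon receptor targets (-0.11, 0.18, up), the respiratory chain (-0.09, -0.04, up), epithelial and endothelial markers (0.01, -0.3, down) and ribosomal proteins (-0.01, 0, up). Polygalae gave aryl hydrocarbon receptor targets (-0.09, -0.21, up) and YAP (0.12, -0.07, down), and Aucklandiae gave metallothioneins (-0.02, -0.11, up). Longan gave neuron (-0.16, 0.04, down) and epithelial markers (0.05, -0.01, up). Zizyphi gave FOXO targets (0.06, -0.01, up), heat shock (0.01, -0.05, down), the unfolded protein response (-0.01, 0.01, down), cholesterol synthesis (0.01, 0, down) and neuron (0.05, 0.09, down) and epithelial markers (0.02, -0.07, down). Liriopis gave LXR targets (0.06, 0.1, down), aryl hydrocarbon receptor targets (0.06, 0.14, down), NF-kB genes (0.05, 0.04, down) and epithelial markers (0.04, -0.02, up).

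Herbs of a shared library set were set against each other at their high doses. Schisandrae exceeded Liriopis for TXNIP (5.23, SE 0.1) and CXCL8 (4.28, SE 0.13), with 4935 genes higher and 5681 lower (10616), and 9684 without Liriopis_high replicate 1, of which 8029 were shared. CXCR5 was lower (-4.72, SE 1.34, adjusted p = 0.0024), and its 37.5 (SD 40.4) CPM in Liriopis_high vary more than their mean. Zizyphi and Longan differed in 180 genes (85 up, 95 down in Zizyphi), with TXNIP (-3.01, SE 0.1) and ARRDC4 (-1.14, SE 0.11) lower and FBXO32 (0.79, SE 0.08) higher in Zizyphi. That total was 508 without Liriopis_high replicate 1, 83 and 81 without Longan_high replicates 1 and 3, and 90, 84 and 103 without Zizyphi_high replicates 1, 2 and 3. Polygalae exceeded Aucklandiae for GDF15 (4.74, SE 0.14) and was lower for TNC (-3.39, SE 0.21) and ANGPTL4 (-2.93, SE 0.1), with 4099 genes higher and 4010 lower (8109), although the doses were 250 and 500 µg/mL.

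**Figure D4:**
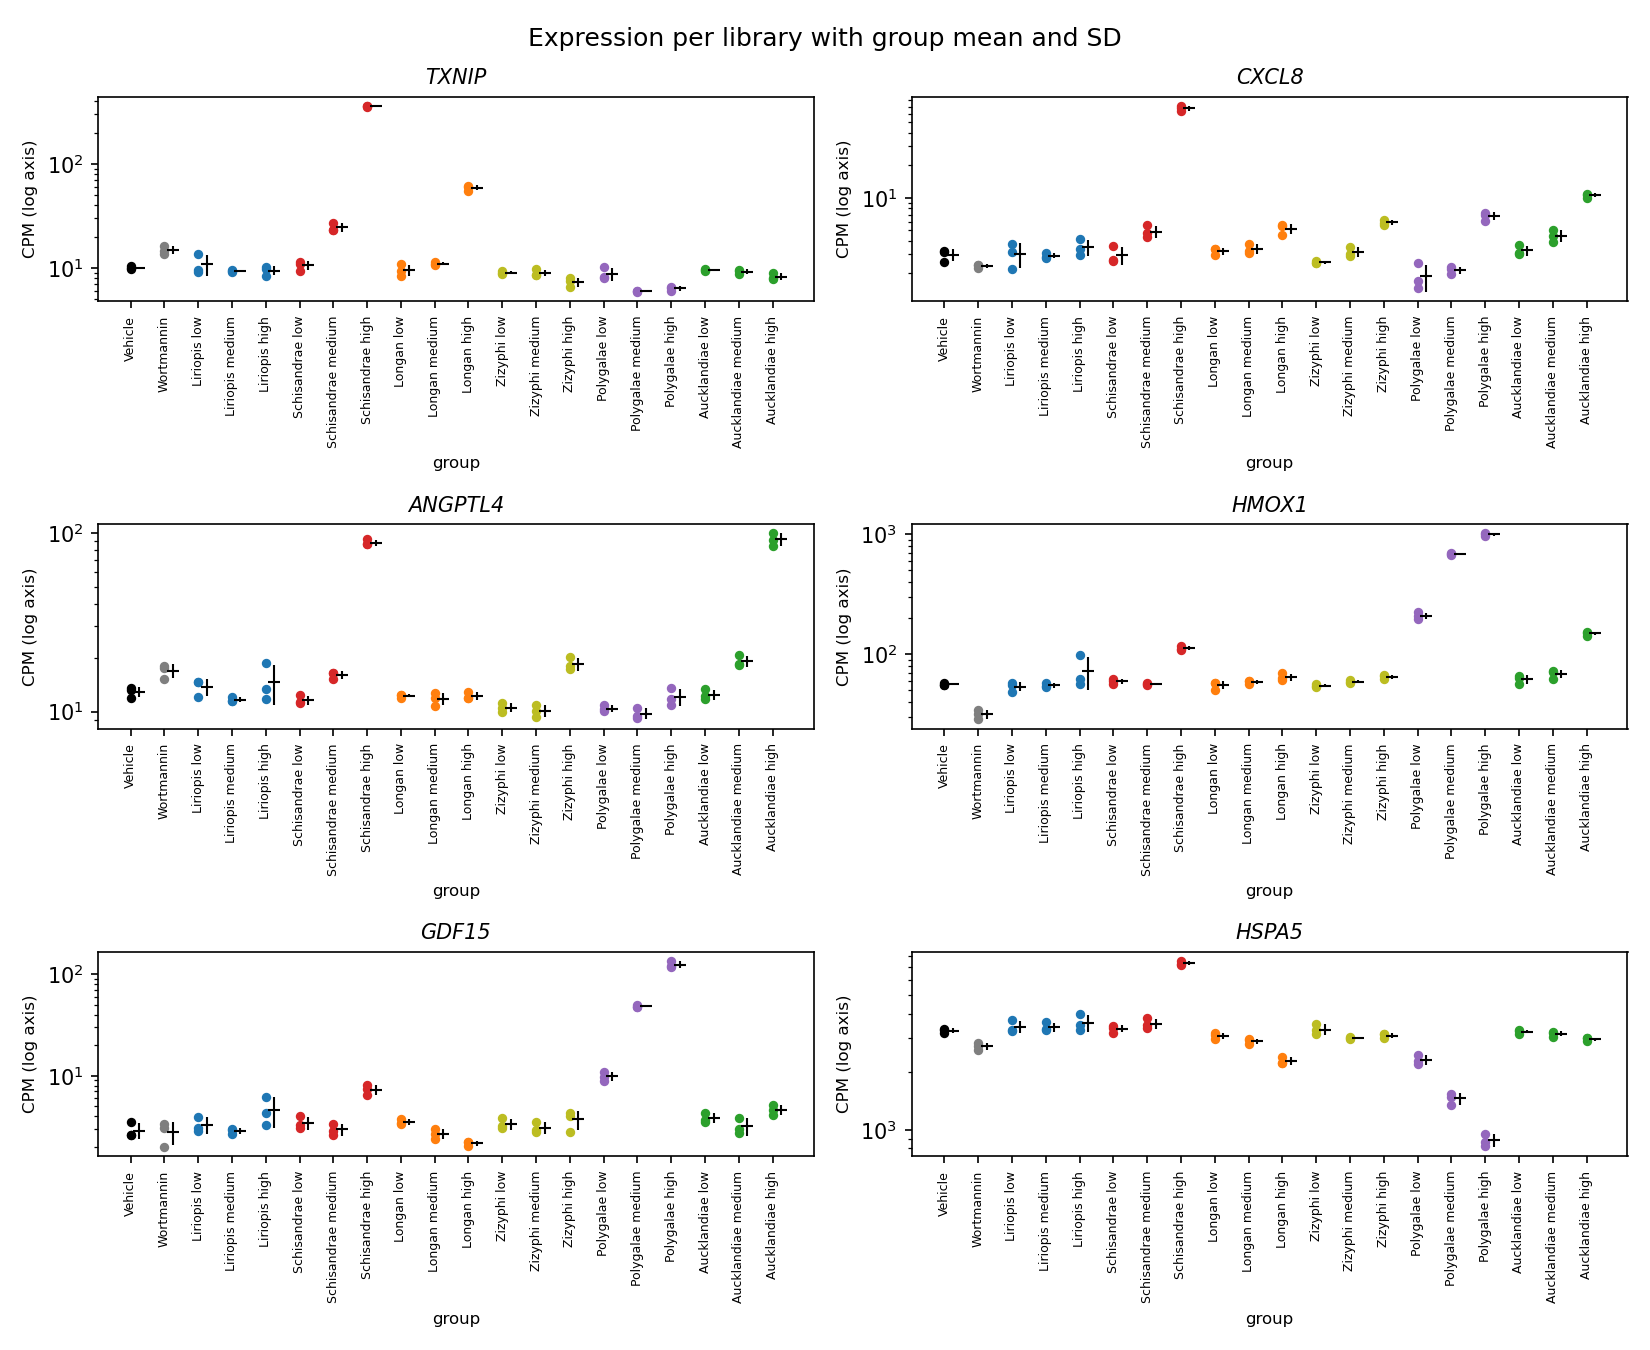
CPM on a log axis (y axis) of 6 genes per library and group (x axis), with group mean and SD of n = 3. TXNIP is high in Schisandrae high (358 CPM) and Longan high (59.2), ANGPTL4 in Schisandrae high (88.2) and Aucklandiae high (91.9), and HMOX1 and GDF15 in Polygalae.

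Some genes answered to several herbs, as seen in comparisons that share no library. Against the low dose of each herb, Schisandrae and Aucklandiae raised 557 of the same genes (236.3 expected if independent) and lowered 607 (233.6 expected), and Schisandrae and Polygalae raised 1259 (794.1) and lowered 1356 (805.3). Polygalae and Aucklandiae raised 371 together (169.4) and lowered 469 (172.3). Opposite directions were rarer for Schisandrae and Aucklandiae, with 95 (235.3) and 148 (234.6) genes. They numbered 714 (811.3) and 665 (788.2) for Schisandrae and Polygalae, and 121 (168.7) and 186 (173) for Polygalae and Aucklandiae. Over all genes, Pearson correlations of fold changes were weak for these pairs in the order given, at 0.17, 0.16 and 0.08 (Spearman 0.27, 0.17 and 0.16). CXCL8 rose from low to high dose in Schisandrae (4.53), Polygalae (1.84), Aucklandiae (1.7), Zizyphi (1.23) and Longan (0.7), and did not pass in Liriopis (0.21, adjusted p = 0.37). Wortmannin and Aucklandiae moved shared genes in opposite directions more often than expected of independent genes, with 230 genes up under wortmannin and down from low to high Aucklandiae (51.4 expected) and 211 the other way (61.7), against 71 (51.6) and 67 (61.5) in the same direction. The Pearson correlation of that pair over all genes was -0.01 (Spearman -0.15). For wortmannin and Schisandrae every direction exceeded the expectation, with 305 (241.8) and 388 (287.3) genes in the same and 330 (240) and 433 (289.5) in opposite directions. An excess over independence is therefore a low bar. These counts are over genes, which are not independent replicates, so no p is given.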

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

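These 3 contrasts between herbs at high dose were planned, and the leave-outs that name a single library were looked at after the counts were seen. Each was picked out because a direct test between 2 herbs of the same library set called genes, so a set difference does not enter. The vehicle libraries enter only through the common dispersion.

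Schisandrae and Liriopis at 500 µg/mL differed in 10616 genes, among them TXNIP (5.23, SE 0.1), CXCL8 (4.28, SE 0.13) and THBD (3.75) upward and CXCR5 (-4.72, SE 1.34), HTR2A (-3.7) and VAV3 (-3.44) downward. CXCR5 varied among the Liriopis_high libraries by more than its mean (37.5 CPM, SD 40.4). Without Liriopis_high replicate 1 there were 9684, of which 8029 are shared with the first count, and in a fit of the 2 groups alone there were 2776. The 10 splits of these 6 libraries cannot reach a share under 0.05, with 1 of them as large, a real value of 2776 and 0 genes as the highest other.

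Zizyphi and Longan at 500 µg/mL differed in 180 genes, with TXNIP (-3.01, SE 0.1), ARRDC4 (-1.14, SE 0.11) and ID3 (-1.03) lower and FBXO32 (0.79, SE 0.08) and ANGPTL4 (0.59) higher in Zizyphi. The count was 508 without Liriopis_high replicate 1, 83 and 81 without Longan_high replicates 1 and 3, and 90, 84 and 103 without Zizyphi_high replicates 1, 2 and 3. Of its 10 splits 1 was as large, too few for a share under 0.05, with a real value of 246 and 9 as the highest other.

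Polygalae at 250 µg/mL and Aucklandiae at 500 µg/mL differed in 8109 genes, with GDF15 (4.74, SE 0.14) higher and TNC (-3.39, SE 0.21), PADI2 (-3.33) and ANGPTL4 (-2.93, SE 0.1) lower in Polygalae. The herb and the dose differ together here, so their parts cannot be separated. Its 10 splits cannot reach a share under 0.05, with 1 as large, a real value of 9182 and 0 as the highest other.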

How the results depend on the processing

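Leaving Liriopis_high replicate 1 out of every comparison was chosen after the data were seen, and the other alternatives were planned. RLE size factors gave the same reading for 28 of 28 gene counts. Taking the replicate number as a block moved 1 of 28 (Aucklandiae low, 2 genes). Over all groups the numbers showed no pairing, with a mean correlation of residuals of 0.0027 for the same number and -0.0014 for different numbers. In 0 of 28 comparisons did all 3 same-number pairs exceed 0.1. In set 2, however, replicate 1 had the lowest TMM factor of every group, such as 0.956 against 0.987 and 0.979 in Schisandrae_high. A pairing within a set therefore cannot be excluded. Keeping low-count genes moved 17 counts, to 1180 for wortmannin, 1 and 0 for Liriopis medium and low, 45 for Schisandrae medium, 48, 1 and 0 for Longan high, medium and low, 59 and 0 for Zizyphi high and medium, 608 for Polygalae low, and 1548, 47 and 3 for Aucklandiae high, medium and low. From low to high dose it gave 17 for Longan, 62 for Zizyphi and 1200 for Aucklandiae, and for Zizyphi against Longan 90. Fits of the compared groups alone moved 15, to 4083 for wortmannin, 0, 0 and 13 for Liriopis high, medium and low, 433 for Schisandrae medium, 479 and 3 for Longan high and low, 4 and 3 for Zizyphi medium and low, 1934 for Polygalae low, and 3726 and 4 for Aucklandiae high and low. From low to high dose they gave 0 for Liriopis and 68 for Longan, and for Schisandrae against Liriopis 2776. DESeq2 moved 8, to 5 for Liriopis low, 3 for Schisandrae low, 341 and 2 for Longan high and low, 13 and 3 for Zizyphi medium and low, and, from low to high dose, 89 for Longan and 187 for Zizyphi. The cause of these changes was not tested.

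Leaving out 1 library at a time gave the same reading in 103 of 193 fits. Against vehicle the counts ran from 1476 to 4108 for wortmannin, from 1 to 8767, 0 to 7 and 0 to 5 for Liriopis high, medium and low, from 8163 to 10601, 73 to 842 and 0 to 0 for Schisandrae, from 37 to 1269, 0 to 10 and 0 to 3 for Longan, from 56 to 420, 0 to 16 and 0 to 1 for Zizyphi, from 7352 to 9760, 4486 to 7308 and 659 to 2512 for Polygalae, and from 1698 to 4126, 45 to 271 and 0 to 16 for Aucklandiae. From low to high dose they ran from 0 to 7371 for Liriopis, 8040 to 10411 for Schisandrae, 13 to 329 for Longan, 68 to 518 for Zizyphi, 5577 to 8265 for Polygalae and 1386 to 3489 for Aucklandiae. Between herbs they ran from 9684 to 11072 for Schisandrae against Liriopis, 81 to 508 for Zizyphi against Longan and 7199 to 9732 for Polygalae against Aucklandiae. Except for the 2 Liriopis_high contrasts with vehicle and low dose and that with Schisandrae, the highest count of each range above 0 came without Liriopis_high replicate 1, which then no longer enters the common dispersion.

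Between Liriopis high and low, the directions of 2 lists were reversed without that library, the nuclear-encoded respiratory chain (adjusted p = 0.72) and cytosolic ribosomal proteins (adjusted p = 0.0026), and the cause was not tested. An estimated correlation kept the reading of 324 of 390 list tests, weakened 65 and strengthened 1. Among 171 named gene results, DESeq2 gave the same reading for 169, keeping low-count genes for 168 and the groups alone for 147. With the groups alone another 22 became weaker and 2 stronger. Leaving out 1 library ended the calls of 118 of 118 named genes for Liriopis high against vehicle, 19 of 33 for Longan, 21 of 93 for wortmannin, 15 of 100 for Aucklandiae, 6 of 26 for Zizyphi, 8 of 124 for Schisandrae and 4 of 120 for Polygalae in at least 1 fit. At the depth of these libraries, 69 of 100 simulated genes changed 2-fold were recovered, and 51 of the 52 with at least 5 CPM, so misses lay mostly at low expression. Other depths were not simulated.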

Other observations

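At the high doses several lists moved with more than a single herb, and no test of a list between herbs was run. Schisandrae raised ATF4 targets (25 up, 0 down of 27), Polygalae raised lysosome genes (21 up, 4 down of 29) and lowered all 23 matrix genes, and Aucklandiae raised NRF2 targets (20 up, 0 down of 24). NRF2 targets rose with Polygalae as well (14 up, 3 down), ERK feedback rose with all 3 of these herbs, and NF-kB genes rose as a list with these 3, Longan and Zizyphi. CXCL8 rose against vehicle with Schisandrae (4.5), Aucklandiae (1.83), Polygalae (1.18), Zizyphi (0.99) and Longan (0.8), and fell at the medium (-0.47, adjusted p = 0.016) and low (-0.66, adjusted p = 0.0061) doses of Polygalae.

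Tests chosen after the result was seen are those of strand, of short transcripts, of the set difference for the matrix genes and TXNIP, and of sugar. Tests of genomic DNA, of other cell types, of transcript length for the matrix genes and all splits were planned before. The value written as going against genomic DNA, a count inside the range of the other libraries, left out that such counts rise with the total of a library (Pearson 0.67), and the comparison with the total was added after the result was seen.

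Liriopis_high replicate 1 stood apart from its replicates, with a mean correlation across genes of 0.945. The SD of its deviations was 1.005, against 0.612 at most in the other libraries and 0.503 at most outside its group. Deviations of Liriopis_high replicates 2 and 3 are taken from a mean that holds replicate 1, so they mirror it. Cells of another type that carry genes absent from the other libraries are argued against. Of protein-coding genes with no gene on the other strand, 0 were over 5 CPM there and under 0.5 CPM in all 59 other libraries. Genomic DNA stays open, since 46 genes without a partner on the other strand were detected there alone. That was inside the range of the others (14 to 51) but above the 29.2 expected from its total and the 21 to 44 of the 10 libraries nearest in total. An excess of short transcripts is a candidate explanation, since the deviation of this library fell with exon length. The Spearman correlation across genes was -0.431, against -0.252 to 0.401 in the other libraries and -0.252 to 0.224 outside its group. Reads assigned without regard to strand cannot be told apart from an excess of short transcripts. The median deviation of 336 genes covered on the other strand was 0.378 (others -0.215 to 0.125, outside the group -0.146 to 0.125), while genes matched to them on length gave 0.617. Yet 39.3% of the covered genes were raised over 2-fold against 32.1% of the matched. Some picked for their rise, such as ZACN (30.8 CPM against 1.65 and 0 in replicates 2 and 3), were nearly absent from the other replicates. No biological explanation was tested, since the design names none for a single library.

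The fall of the matrix genes with Polygalae_high had a median of -1.25. Transcript length is argued against as the whole account, as the lowest median of 10000 lists matched on exon length was -0.59. A set difference is argued against as well, since 23 of 23 fell between high and low dose in a single set. An effect of the extract on matrix genes may remain as a hypothesis, found and tested on the same data.

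TXNIP rose with Longan_high and Schisandrae_high, and for Longan a set difference is argued against, with a log2 fold change of 2.63 between doses of a single set. More sugar reaching the cells is a possible explanation for Longan, where the unfolded protein response, which rises when glucose is scarce, fell (adjusted p = 0.00029 with an estimated correlation). That list was chosen as a test of sugar after the results were seen, so its fall describes these data and is no separate support. The rise of TXNIP and the fall of that list may not be particular to sugar. Against vehicle, wortmannin libraries had higher TXNIP (0.57, adjusted p = 3.3e-05) and lower HSPA5 (-0.27, adjusted p = 0.0014). ARRDC4 did not pass there (0.15, adjusted p = 0.45), and drug and library set cannot be told apart in that contrast. From low to high Polygalae, HSPA5 fell (-1.39, adjusted p = 4.1e-23) and TXNIP fell too (-0.46, adjusted p = 0.00051). For Schisandrae the unfolded protein response list rose (adjusted p = 0.0056 with an estimated correlation). That is the opposite of what sugar alone would give, in a test also chosen after the results were seen. Another constituent could raise that list by itself, and no label gives a sugar content.

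Every comparison of 3 against 3 libraries has 10 splits, so a share under 0.05 cannot be reached, and the counts here are from fits of the 6 libraries alone. With the real value first and the highest other split second, these were 4083 and 0 for wortmannin, 10176 and 0, and 433 and 2, for Schisandrae high and medium, 479 and 1 for Longan high, 9049 and 0, 5775 and 0, and 1934 and 0 for Polygalae high, medium and low, 3726 and 1 for Aucklandiae high, and 13 and 1 for Liriopis low, each with 1 split as large, the real one. From low to high dose they were 9955 and 0 for Schisandrae, 68 and 1 for Longan, 133 and 3 for Zizyphi, 7654 and 0 for Polygalae and 2759 and 1 for Aucklandiae, again with 1 as large. For Liriopis high (0 and 0), Liriopis medium (0 and 2), Schisandrae low (0 and 2) and Liriopis high against low (0 and 0), 10 of 10 splits were as large. Zizyphi low had 3 and 3, with 3 as large.

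In 6 comparisons 2 of the 10 splits were as large, the other one placing Vehicle replicate 1 with 2 treated libraries. Real and highest other values were 5 and 869 for Longan medium and 3 and 1022 for Longan low (treated replicates 2 and 3), 152 and 180 for Zizyphi high and 4 and 638 for Zizyphi medium (replicates 1 and 3), and 115 and 217 for Aucklandiae medium and 4 and 935 for Aucklandiae low (replicates 1 and 2). Splits that call several times the real count point to a structure of these samples across the groups, which no label names. In each of the 6, the 2 treated libraries placed with Vehicle replicate 1 had a lower correlation of deviation and exon length than the treated library left out of that side. For Vehicle replicates 1, 2 and 3 it was -0.249, 0.019 and 0.224, for Longan low 0.1, -0.068 and -0.082, for Zizyphi medium -0.018, 0.117 and -0.124, and for Aucklandiae low -0.172, -0.059 and 0.188. This was seen after the splits, and no fit with length taken out was run. The cause of the structure was not tested, and small counts against vehicle should be read with it.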
